A study of Bacillus subtilis with 16 samples.

How the data were processed

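Gene expression of *Bacillus subtilis*, a Gram-positive soil bacterium, was measured on 8 two-colour Agilent arrays, all on 1 slide. Fusaricidin is a lipopeptide antibiotic made by *Paenibacillus* species. Per the labels, a culture in LB medium was divided, 1 part received fusaricidin, and RNA came from separate cultures at each time point; the dose is not given in the sources used here. Each array held Cy3-labelled RNA of 1 sample and Cy5-labelled RNA of untreated cells at 0 min, so the 16 samples are the 2 channels of 8 arrays. The Cy3 samples were untreated at 5 min, or treated at 5, 20 or 170 min, with 2 arrays per group. The dyes were never swapped, per the labels. A dye effect of a gene therefore stays in every ratio to 0 min and cancels when 2 Cy3 groups are compared. No untreated culture of 20 or 170 min was analysed here.

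The scanner files hold a Cy3 and a Cy5 intensity per spot, made with Agilent Feature Extraction 10.5.1.1, per the file headers. The file of each Cy3 sample was identical to that of its Cy5 partner on all 8 arrays, and each channel was taken once. The processed intensity in the same files was background-subtracted and dye-normalized within the array by that program, per the file headers. The authors' deposited tables give a log2 ratio of Cy3 over Cy5 for 12278 probes; every value lay within 0.02 of the log2 ratio of the processed signals, the largest difference being 0.0122. Their mean per group is the log2 of the mean of the linear ratios. The authors' deposited flags (unit: other, 0 or 1 per spot) mark spots well above background, saturated spots and outliers.

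The array carried 15744 spots, of which 536 were controls. Of 12312 spots for genes with a BG identifier, 34 were not analysed here, which left 12278 probes of 4101 genes; 4080 of these genes had 3 probes. Another 2896 spots were 26 or 27 copies each of 108 probes with a Bsu identifier, which were kept out of the gene tests. The files do not pair these identifiers with gene names, and 0 of the 4212 identifiers matched a locus tag, symbol or accession among the 4536 genes of the reference table for assembly ASM904v1. Genes are therefore given by identifier. The 40 gene lists fixed before the data were examined could not be tested, since 0 of their members matched, and the genes fixed in advance to be named in every comparison could not be found. The rule for naming genes asked for these, for members of changed lists, and for the largest rises and falls past the threshold on arrays without overlap. It was shortened to at most 2 genes that rose and 2 that fell per comparison, because the identifiers could not be named.

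Mean foreground was corrected with the median local background by limma's normexp method with an offset of 50, and log2 ratios of Cy3 over Cy5 were normalized within each array by loess with control spots at weight 0. Spots flagged as outliers were left out, a median of 0.0122% of spots per array and at most 0.375%. Copies of a probe and then the probes of a gene were averaged. A gene was kept when a probe was well above background in Cy3 on both arrays of at least 1 group or in Cy5 on all arrays; all 4101 genes passed. No spot was saturated. One limma 3.58.1 fit over all 8 arrays gave a mean per Cy3 group with 4 residual degrees of freedom, and moderated tests were adjusted by Benjamini-Hochberg over 4101 genes, with 0.05 as the threshold. R 4.3.3 and version 1.17.8 of the data.table package were used. The standard error (SE) of a change comes from this fit, and the SD from the 2 arrays of a group. The number of arrays limits the precision.

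The fit was tested on simulated arrays for the comparison of treated and untreated cells at 5 min, with 200 of 4101 genes changed in 5 simulations. It found 51.2% of the genes changed 2-fold and 98% of those changed 4-fold, and 3.74% of its calls were false. The simulated arrays had the same spread per gene in all groups and independent errors. The real groups differed in spread and the treated replicates deviated together, so these rates may not hold for the real comparison. The estimated changes were 0.885 times the simulated ones for 2-fold genes and 0.886 times for 4-fold genes. Without the offset these ratios were 1.03 and 1.06, so the offset shrank the simulated changes. On the real arrays an offset of 0 moved the log2 change between treated and untreated cells at 5 min little, from 4.77 to 4.86 for BG13946 and from 3.87 to 3.98 for BG13947. The genes named below were picked for their large changes, which can make their folds lean high.

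The 0 min channel enters the ratios without a spread of its own. Its levels correlated across genes at 0.996 to 0.999 between arrays, with a root-mean-square SD of 0.081 (log2). The labels number 8 untreated 0 min samples but do not say whether they are 1 RNA or several cultures. The simulations below and the remarks on a shared 0 min RNA assume 1 RNA. In 20 simulations with no change and no error in the 0 min RNA, no comparison had more than 2 calls. When the 0 min RNA was given the spread of 1 further sample, the 4 comparisons with 0 min had medians of 138.5 to 158.5 calls. For lists of calls that share the 0 min RNA, the overlap expected of independent lists and the overlap in such simulations are given beside the observed one. The simulated lists are far shorter than the observed ones, so their overlap does not measure how much the 0 min RNA adds.

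The alternatives set before the data were examined were no background subtraction, the processed signals, median centring, the authors' deposited log2 ratios, no filter, the brightest probe of each gene, saturated spots left out, a 2-fold minimum, the arrays of the compared groups alone, the replicate number as a block, each array left out, the Cy3 channel alone, and the untreated 5 min arrays as the baseline. Slide row as a block, array weights, an offset of 0 and an intensity trend in the variance were added after the data were seen.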

Results

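The response of *B. subtilis* to fusaricidin was followed on 8 arrays, with 2 arrays each for untreated cells at 5 min and for treated cells at 5, 20 and 170 min, every array against untreated cells at 0 min. The median foreground signal of the Cy3 channel ran from 254.4 in replicate 2 of the treated 5 min group to 1821 in replicate 1 of the treated 20 min group, while that of the 0 min channel ran from 541.6 to 707.4. At least 99.85% of the probes were well above background in either channel of every array. Copies of 1 probe on an array had log2 ratios with a median SD of 0.07 to 0.082. Replicate arrays correlated across genes at 0.98 for untreated 5 min, 0.872 for treated 5 min, 0.858 for treated 20 min and 0.931 for treated 170 min. The spread between replicates was 0.14 (root-mean-square SD, log2) for the untreated group and 0.303, 0.34 and 0.276 for the treated groups in order of time. The fit shares 1 spread per gene among the groups. On average this is too wide for the untreated group and too narrow for the treated 5 and 20 min groups. Genes carry the identifiers of the array, which the files do not pair with names.

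**Figure D1:**
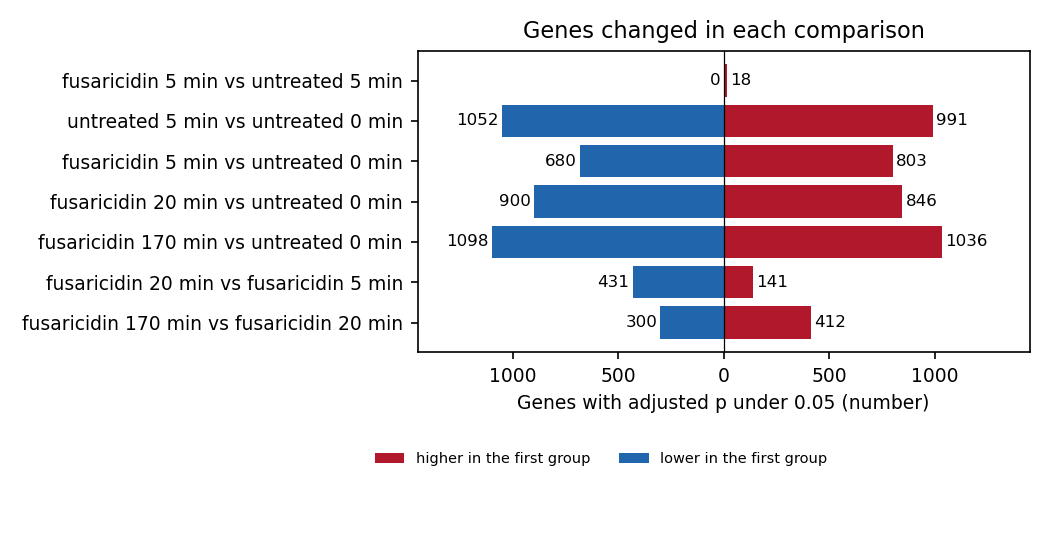
Number of genes with a limma adjusted p under 0.05 in each comparison (horizontal axis), with genes higher in the first-named group to the right in red and genes lower in it to the left in blue. Treated and untreated cells at 5 min differed in 18 genes, all higher with fusaricidin (20 higher and 345 lower with median centring in place of loess), and the comparisons with 0 min gave 1483 to 2134 genes.

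The effect of fusaricidin itself is measured most directly at 5 min, the single time with both treated and untreated cells. At that time 18 of 4101 genes differed, and all 18 were higher in treated cells, by 1.11 to 4.77 on the log2 scale with a median of 1.98. BG13946 rose most, 27.3-fold (log2 change 4.77, SE 0.54, limma adjusted p = 0.011). Its ratio to 0 min was −0.37 ± 0.22 in untreated and 4.40 ± 0.92 in treated cells (log2, SD, n = 2). BG13947 rose 14.7-fold (log2 change 3.87, SE 0.22, limma adjusted p = 0.00038), from 0.62 ± 0.05 to 4.50 ± 0.25 (log2, SD, n = 2). The 4 arrays did not overlap in any of the 18 genes, but this held for every call in all 7 comparisons and is no separate support. The probes of each of the 18 genes moved in 1 direction. No gene was lower in treated cells at the limma adjusted threshold, while 296 genes were lower and 369 higher at an unadjusted p under 0.05. This count rested on few arrays: it was 2 without untreated replicate 1 and 4 without untreated replicate 2, and BG13946 then missed the threshold (adjusted p = 0.21 and 0.13), whereas BG13947 passed it in each alternative run. Median centring in place of loess gave 20 genes higher and 345 lower, a slide-row block 33 higher and 2 lower, and array weights 26 higher and 6 lower. A block over the replicate numbers, given with the alternatives below, also added calls in both directions.

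**Figure D2:**
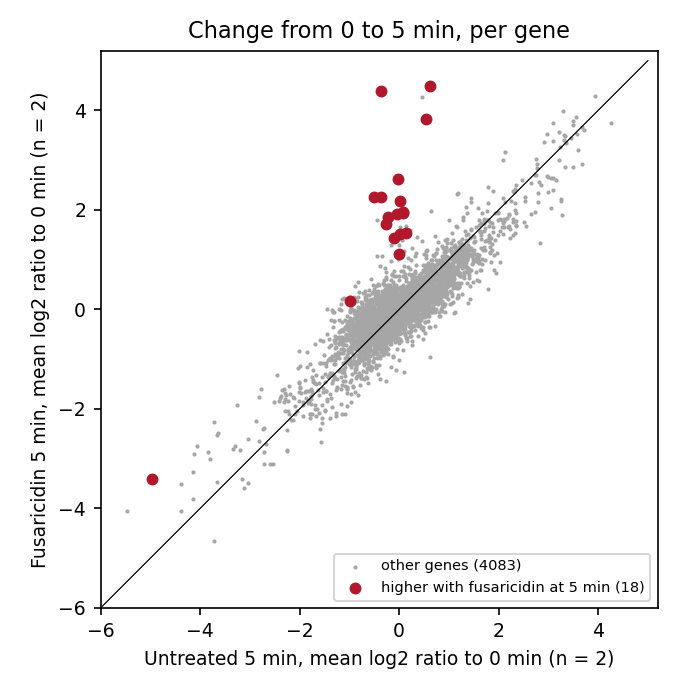
Mean log2 ratio to 0 min of each gene in untreated (horizontal axis) and treated cells (vertical axis) at 5 min, each the mean of 2 arrays, with the line of equal change in black. The 18 genes that differed are red and lie above the line (with median centring in place of loess, 345 of 365 genes that differed were lower in treated cells); most genes moved alike in both groups.

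The 18 genes were followed into the later times. Their median log2 ratio to 0 min was −0.035 in untreated cells at 5 min and 1.93 in treated cells at 5 min, and then 0.10 at 20 min and 0.21 at 170 min. From 5 to 20 min under treatment 16 of the 18 fell past the limma threshold. The exceptions stood higher at 20 min than at 5 min. Among them was BG12829, at −3.41 ± 0.32 at 5 min and −2.93 ± 0.26 at 20 min under treatment (log2, SD, n = 2). Its ratio was thus below 0 min in treated cells too. BG13946 stood at 0.84 ± 0.44 at 20 min and BG13947 at 1.20 ± 0.32 (log2, SD, n = 2). Against untreated cells at 5 min, 4 of the 18 were higher at 20 min and 4 at 170 min. Among all 4101 genes, 805 were higher at 20 min and 585 at 170 min in these comparisons. The counts of 4 alone therefore do not show a lasting rise particular to the 18. Both comparisons behind the count of 16 use the treated 5 min arrays, and part of the count may come from their noise. Independent lists of these sizes would share 1.89 genes; simulations with no change made at most 1 call per comparison, so they do not measure that part.

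**Figure D3:**
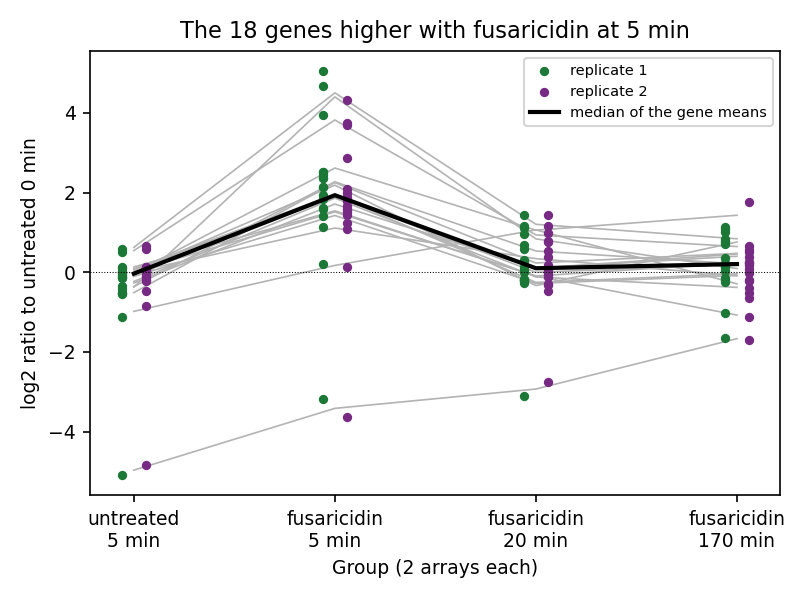
Log2 ratio to untreated 0 min (vertical axis) of the 18 genes higher with fusaricidin at 5 min, by group; dots are the 2 arrays of each group, grey lines join the means of 1 gene and the black line joins their medians. The median was 1.93 in treated cells at 5 min and 0.10 at 20 min.

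Untreated cells at 5 min were compared with 0 min to see what changed without the compound. Of 4101 genes, 2043 changed, 991 up and 1052 down, and 690 of them changed at least 2-fold, 414 up and 276 down. BG10826 rose 19.2-fold (log2 change 4.26, SE 0.21, limma adjusted p = 4.4e-06) and BG12886 rose 15.4-fold (log2 change 3.94, SE 0.13, limma adjusted p = 1.4e-06). BG11926 fell 44.6-fold (log2 change −5.48, SE 0.28, limma adjusted p = 4.7e-06). BG12829 fell 31.2-fold (log2 change −4.96, SE 0.15, limma adjusted p = 1.4e-06) and was among the 18 genes higher with fusaricidin, at −3.41 ± 0.32 in treated cells (log2, SD, n = 2). These ratios hold any dye effect and leave out the spread of the 0 min RNA. Median centring gave 1238 up and 1043 down. With 1 untreated array left, 810 genes passed without replicate 1 and 1270 without replicate 2, and with these 2 arrays alone in the fit 3077 passed.

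Treated cells at 5 min differed from 0 min in 1483 genes, 803 up and 680 down, of which 582 changed at least 2-fold. The largest rises were those of BG13947 (22.6-fold, log2 change 4.50, SE 0.16, limma adjusted p = 1.7e-06) and BG13946 (21.1-fold, log2 change 4.40, SE 0.39, limma adjusted p = 8.4e-05). BG19003 fell 25.2-fold (log2 change −4.66, SE 0.33, limma adjusted p = 3.1e-05) and BG12469 fell 16.6-fold (log2 change −4.06, SE 0.19, limma adjusted p = 4.8e-06). Both of these also stood low in untreated cells at 5 min, at −3.72 ± 0.07 and −4.38 ± 0.09 (log2, SD, n = 2). Neither passed the limma threshold between treated and untreated cells (log2 difference −0.94, adjusted p = 0.34, and 0.32, adjusted p = 0.53). The treated 5 min replicates of BG19003 were wide (SD 1.2, log2, n = 2), so a difference in this gene is not excluded. Of the 1483 genes, 1234 changed in the same direction in untreated cells and 1 in the opposite direction. Independent lists would share 368 in the same direction, and simulations with no change and a shared 0 min RNA gave a median of 52. The simulated lists held medians of only 150.5 and 155 calls, so the 52 does not measure how much that RNA adds to the 1234. Part of the overlap may come from that RNA and the dyes. Without treated replicate 2 of this time 826 genes passed, and with median centring the split was 577 up and 774 down.

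At 20 min, treated cells differed from 0 min in 1746 genes, 846 up and 900 down, and 624 changed at least 2-fold, 206 up and 418 down. BG12012 rose 13.8-fold (log2 change 3.79, SE 0.30, limma adjusted p = 3.9e-05). BG13419 rose 11.2-fold (log2 change 3.48, SE 0.69, limma adjusted p = 0.0047), with wide replicates in each treated group (SD 1.9 at 5 min, 1.3 at 20 min and 1.3 at 170 min, log2, n = 2), and it missed the threshold without replicate 1 of this time (adjusted p = 0.068). BG19003 fell 92.7-fold (log2 change −6.53, SE 0.33, limma adjusted p = 8.7e-06) and BG12471 fell 62.3-fold (log2 change −5.96, SE 0.12, limma adjusted p = 1.5e-07). With the untreated 5 min arrays as the baseline the log2 changes were 1.71 for BG12012, 3.03 for BG13419, −2.82 for BG19003 and −2.62 for BG12471. Of the 1657 genes that passed with this baseline, 756 were among the 1746 in the same direction. The small excess of falls among all 1746 turned with the scaling, to 1007 up and 769 down from the processed signals and 1007 up and 770 down from the authors' deposited log2 ratios, and also with a slide-row block (1184 up, 1017 down) and without replicate 1 of this time (923 up, 781 down). A block over the replicate numbers, given with the alternatives below, turned the excess of falls as well. Time and treatment cannot be separated here, since untreated cells of this age were not analysed.

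At 170 min, treated cells differed from 0 min in 2134 genes, 1036 up and 1098 down, and 888 changed at least 2-fold. BG12012 stood 18.9-fold higher (log2 change 4.24, SE 0.30, limma adjusted p = 1.6e-05) and BG10849 18.6-fold higher (log2 change 4.21, SE 0.12, limma adjusted p = 3e-07). BG12671 fell 630-fold (log2 change −9.30, SE 0.24, limma adjusted p = 2.6e-07), from −1.69 ± 0.07 in untreated and −1.93 ± 0.63 in treated cells at 5 min through −4.73 ± 0.06 at 20 min (log2, SD, n = 2). BG12471 fell 217-fold (log2 change −7.76, SE 0.12, limma adjusted p = 1.9e-08). With the untreated 5 min arrays as the baseline in place of 0 min, 1318 genes passed, 585 up and 733 down. Of these, 887 were among the 2134 in the same direction. The log2 changes were then 2.16 for BG12012, 4.29 for BG10849, −7.61 for BG12671 and −4.43 for BG12471. The small excess of falls turned to 1095 up and 1030 down with the processed signals and to 1069 up and 826 down with median centring. As at 20 min, the age of the culture is confounded with the treatment.

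From 5 to 20 min under treatment 572 genes changed, 141 up and 431 down, with 64 of the rises and 285 of the falls at least 2-fold. Replicate differences of these groups correlated across genes at 0.59, which the fit does not take into account. A block over the replicate numbers, given with the alternatives below, raised the count. BG12886 fell 21.4-fold (log2 change −4.42, SE 0.19, limma adjusted p = 1.5e-05), from 4.30 ± 0.16 to −0.12 ± 0.22 (log2, SD, n = 2), after it had risen in untreated and treated cells at 5 min alike. BG10736 fell 17.8-fold (log2 change −4.15, SE 0.16, limma adjusted p = 1.2e-05), from 3.71 ± 0.11 to −0.44 ± 0.15 (log2, SD, n = 2). In untreated cells at 5 min BG10736 also stood high, at 3.49 ± 0.02 (log2, SD, n = 2). Untreated cells at 20 min were not analysed, so time and treatment cannot be separated in these changes. BG12075 rose 5.06-fold (log2 change 2.34, SE 0.22, limma adjusted p = 0.00039) and BG14024 rose 4.91-fold (log2 change 2.30, SE 0.18, limma adjusted p = 0.00014). The split between rises and falls changed under some scalings, with 215 up and 345 down from the processed signals, 214 up and 345 down from the authors' deposited log2 ratios, and 388 up and 341 down from the Cy3 channel alone. With only the arrays of these groups 262 genes passed, with a slide-row block 884, with median centring 356 (90 up and 266 down, close to the main split), and without treated 5 min replicate 1 the count was 331.

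From 20 to 170 min under treatment 712 genes changed, 412 up and 300 down. Untreated cells of these ages were not analysed, so time and treatment cannot be separated. Replicate differences of these groups correlated across genes at 0.67, which the fit does not take into account. A block over the replicate numbers, given with the alternatives below, raised the count and ended the excess of rises. BG13852 rose 19.8-fold (log2 change 4.31, SE 0.25, limma adjusted p = 0.00029) and BG13851 rose 15.3-fold (log2 change 3.93, SE 0.25, limma adjusted p = 0.00029). BG13852 stood at 1.12 ± 0.23 at 5 min under treatment, −2.72 ± 0.51 at 20 min and 1.58 ± 0.06 at 170 min, and BG13851 at 0.87 ± 0.35, −3.02 ± 0.42 and 0.91 ± 0.13 (log2, SD, n = 2). BG12671 fell 23.7-fold (log2 change −4.57, SE 0.33, limma adjusted p = 0.00037) and BG13672 fell 14.2-fold (log2 change −3.82, SE 0.41, limma adjusted p = 0.001). The excess of rises followed the processing: median centring gave 591 up and 155 down, and the log2 change of BG12671 was then −3.01. Falls outnumbered rises with the brightest probe of each gene (285 up, 343 down), with the Cy3 channel alone (310 up, 333 down) and with a slide-row block (589 up, 625 down). Fewer genes passed with only the arrays of these groups (313), with array weights (393), and without untreated 5 min replicate 1 or 2 (432 each), treated 20 min replicate 2 (413), treated 170 min replicate 1 (279) or replicate 2 (390), and more with a slide-row block (1214).

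In the authors' deposited tables, the mean log2 ratio to 0 min was at least 1 for 1449 probes and at most −1 for 1262 probes in untreated cells at 5 min. The corresponding numbers for treated cells were 1246 and 941 at 5 min, 1145 and 1242 at 20 min, and 1752 and 1442 at 170 min. With the mean of the 2 log2 ratios in place of the authors' mean of linear ratios, the treated 20 min arrays gave 995 and 1285 probes.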

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

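The tests of chance highs among the genes higher at 5 min, of chance placing of consecutive identifiers and of pairs without shared sequence were chosen after the result was seen.

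The ratio to 0 min differed between treated and untreated cells at 5 min in 18 genes, between treated cells at 20 and 5 min in 572 genes and between treated cells at 170 and 20 min in 712 genes, each by the test of that difference. Probes with a Bsu identifier, which no comparison of the report uses, also changed against 0 min: of 108 such probes, 50 in untreated cells at 5 min, and 42, 51 and 61 in treated cells at 5, 20 and 170 min. Between 5 and 20 min under treatment 27 of them changed, 1 up and 26 down, and between 20 and 170 min 27, 25 up and 2 down. Between treated and untreated cells at 5 min, limma called 0 of the 108 after adjustment and 27 at an unadjusted p under 0.05. For 31 pairs of a Bsu probe and a BG gene whose probes share 20 bases, log2 ratios correlated across pairs at 0.85 to 0.95 on each array.

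At 20 min the median of the 18 genes was near its untreated 5 min level, and 16 of them had fallen past the limma threshold. If the genes had been picked for chance highs, genes picked on the replicate 1 arrays alone would show little change on the replicate 2 arrays. The 18 genes with the largest rise on replicate 1 (12 of them among the 18 called) had a median change of 1.76 on replicate 2 (log2), above 0 for all 18. All genes had a median of 0.03 there, with an SD of 0.53 between single genes, which is not the spread of a median. These values argue against chance highs. At 20 min on replicate 2, 17 of these 18 stood lower than at 5 min. A short-lived response to the compound remains a hypothesis, because untreated cells at 20 min were not analysed.

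Among the 18 genes, 9 had identifiers in 3 runs of consecutive numbers, which made 6 consecutive pairs. The permutation p was 1e-05, the smallest that 100000 random draws of 18 genes can give, and no draw had more than 3 pairs, which argues against chance placing. The probes of 1 pair shared a stretch of 20 bases, so shared signal stays open for that pair, and those of the other 5 did not. The pairs' probes lay a median of 26.1 spot positions apart. Medians of random sets of 6 pairs had a median of 21.2 and a 5th percentile of 12.1, which argues against neighbouring spots. Genes with consecutive identifiers may be neighbours that are transcribed together; the files give no gene positions, so this was not tested.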

How the results depend on the processing

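Slide row, array weights, an offset of 0 and an intensity trend were chosen after the data were seen. The 7 counts stayed within 1.5 times under no background subtraction, the processed signals, the authors' log2 ratios, the brightest probe, an offset of 0 and an intensity trend, and the 3 without 0 min also with Cy3 alone. No filter and no saturated spots changed nothing, since neither removed a value. No alternative for the gene lists could give a value. Of 26 changes of named genes, 22 passed in every alternative; BG12469 at 5 min against 0 min turned to 0.32 with untreated 5 min as the baseline. With signals well above background, depth did not limit which genes were tested. Median centring gave 365 genes for treated against untreated at 5 min (11 of the 18 among them) and 356 from 5 to 20 min. At 5 min the change then correlated with intensity across genes at −0.72 (Spearman; −0.14 with loess), and the median of all genes was −0.21 against 0.029. From 5 to 20 min that median was 0.14 with the processed signals and 0.20 with Cy3 alone, against 0.029. At least 2-fold changes numbered 690, 582, 624 and 888 against 0 min (untreated 5 min, then treated in order of time), 349 from 5 to 20 min and 330 from 20 to 170 min. The arrays of the compared groups alone gave 3077 for untreated 5 min against 0 min, 262 from 5 to 20 min and 313 from 20 to 170 min, with fewer arrays in the fit. Fewer arrays alone would not raise the first count from 2043. The main fit shares 1 spread per gene among groups whose replicate SDs were 0.14 (untreated), 0.303, 0.34 and 0.276 (treated, in order of time). It thus overstates the spread of the untreated group and understates that of the treated 5 and 20 min groups. The untreated 5 min baseline gave 1318 genes at 170 min, 887 of them among the 2134 main calls in the same direction. At 5 min this baseline is the comparison of treated and untreated cells itself, so its 18 genes are no separate result. Slide row as a block gave 35, 884 and 1214 for the 3 comparisons without 0 min, and array weights 32 at 5 min and 393 from 20 to 170 min. The cause of these moves was not tested further. The replicate block gave 314 genes (218 up, 96 down; all 18 among them) at 5 min, 1016 (363 up, 653 down) from 5 to 20 min, 1280 (639 up, 641 down) from 20 to 170 min and 2299 (1260 up, 1039 down) at 20 min against 0 min. Replicate differences correlated across genes at −0.01 to 0.19 between untreated and treated groups and 0.59 to 0.70 among treated ones. The treated replicates thus deviated together by number, which the main fit ignores, and the untreated ones little with them. The numbers were therefore not taken to pair all arrays. Leaving out 1 array, which assumes that a lone array varies like the rest, gave 2 (without untreated replicate 1), 4 (without untreated replicate 2) to 16 genes for treated against untreated at 5 min, 810 to 2260 for untreated 5 min against 0 min, 826 to 1619 for treated 5 min against 0 min, 331 to 487 from 5 to 20 min and 279 to 737 from 20 to 170 min. Without treated 5 min replicate 1, 3 of 13 genes at 5 min were lower.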

Other observations

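All tests in this part were chosen after the result was seen.

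Several groups of genes moved 1 way and then back. Of 431 genes that fell from 5 to 20 min under treatment, 77 rose from 20 to 170 min, where independent lists would share 43.3, and of 141 that rose from 5 to 20 min, 51 then fell, against 10.3 for independent lists. Both comparisons use the treated 20 min arrays, whose noise adds to these opposite calls; simulations with no change made at most 1 call per comparison, so they do not measure how much. Of 1746 genes that differed from 0 min at 20 min, 1216 also differed in the same direction at 170 min and 66 in the opposite direction; independent lists would share 455, and simulations with no change and a shared 0 min RNA 47.5. In untreated cells at 5 min and treated cells at 170 min, each against 0 min, 188 genes changed in opposite directions and 1112 in the same. Independent lists would share 532 in the same direction and the simulations 45. The number of opposite calls expected of independent lists was not computed here, so 66 and 188 do not show a return. The simulated lists were far shorter than the observed ones, so 47.5 and 45 do not measure how much the 0 min RNA adds.

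Changes of genes with consecutive identifiers correlated across 4011 pairs in each of the 7 comparisons, at 0.33 between treated and untreated cells at 5 min and at 0.37 to 0.41 in the others. The highest absolute value in 1000 shuffles of the genes was 0.058. Genes are not independent replicates, and shared sequence was not tested for these pairs.

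The difference between replicates 1 and 2 was shared by the 3 treated groups, and lay in the Cy3 channel, where it correlated across genes at 0.61 to 0.71 between times. The Cy5 channels gave at most 0.13, which argues against the 0 min reference. The treated 170 min arrays share a slide row, yet their difference correlated at 0.77 with the mean of the other times, which argues against the row as the whole cause. After a smooth fit on intensity and GC content the lowest correlation was 0.57, which argues against these too. Replicate 2 minus replicate 1, averaged over the treated times, correlated across genes at 0.49 with the change between treated and untreated cells at 5 min, but the treated 5 min arrays enter both. A difference between the treated cultures may remain, and no test here separates it from RNA handling or labelling that followed the replicate number.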
